A study of Homo sapiens with 7 samples.

How the data were processed

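Hi-C was measured in 7 libraries of DLD-1 cells, an established colorectal adenocarcinoma line, made with an Arima Hi-C kit and sequenced as read pairs, per the labels' protocols. Auxin (indole-3-acetic acid) was given for 4 or 10 d, per the labels' protocols, and 1 library followed 4 d of auxin by 4 d of washout. Reads were mapped to hg38 with BWA, per the submitters' processing notes. The version of BWA, the filtering of read pairs, and the programs that balanced the matrices and made the tables are not given in the sources used here.

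The values come from tables of contact by separation. For each library and each separation in steps of 50 kb, the deposited tables give the count of raw contacts, the sum of the balanced signal and the number of valid bin pairs, per the file headers, within chromosome arms, within whole chromosomes, between the arms of a chromosome and, without separation, for each pair of chromosomes. The count values are whole numbers and not normalised, per the file headers and the values themselves. The deposited balanced signal is the authors' matrix-balanced contact. Balancing gives every bin the same total, so a balanced value says how a bin's contacts are spread over partners, not how many contacts it has, and a chromosome with more copies is not scaled back pair by pair. The smallest separation with values was 100 kb (2 bins), so contacts closer than that enter no share. For the untreated DNMT1-AID library the authors also deposited k-means clusters of 50 kb bins as names and codes, merged from 9 clusters to 5 names. The eigenvector means per cluster that had been planned could not be computed from the values used here.

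Chromosomes 1 to 22 and X were used (23 chromosomes), and chromosomes Y and M were left out. From raw counts, the trans share is the share of contacts between chromosomes among all contacts, and the shares at 10 Mb or more and under 1 Mb are shares of contacts within arms. Each has a 95% exact binomial (Clopper-Pearson) interval, which covers counting error only. From balanced values, the inter-arm ratio is the mean contact per valid bin pair between arms over that within arms, both at 20 to 50 Mb, on the 18 chromosomes with at least 10000 bin pairs of each kind. The pooled ratio lies below the ratio at equal separation, since inter-arm pairs in this range lie farther apart. In simulated libraries with a ratio of 0.8 at every separation it was 0.709, while matching each separation gave 0.798. The decay exponent is the least-squares slope of log10 contact on log10 separation over 20 log-spaced bins between 0.5 and 5 Mb. Arms entered with at least 1000 counts. For 3 lists of 5 chromosomes, the mean balanced contact of the 10 pairs within the list was divided by that of all other pairs, and its log2 difference between libraries was ranked among all 33649 sets of 5 chromosomes. These sets were not matched for their untreated contact. All values are given as log2 ratios or differences between libraries. The 11 comparisons are 4 d, 10 d and washout against untreated and 10 d and washout against 4 d in DNMT1-AID cells, 4 d and 10 d against untreated and 10 d against 4 d in knockout cells, and knockout against DNMT1-AID cells untreated, at 4 d and at 10 d. The difference of the auxin effects between the genotypes was taken at 4 d and at 10 d.

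Each group holds 1 library, so no difference between groups was tested against replicates. Only the knockout and DNMT1-AID libraries at the 3 shared times were also taken as pairs, after seeing the data, with an exact two-sided permutation test of signs over 3 pairs that assumes the same difference at each time and cannot go below p = 0.25. The number of chromosomes, arms or pairs with a direction and their SD describe these libraries only. Depth ranged from 27345260 contacts (washout) to 222645438 (4 d of auxin, DNMT1-AID), and the counting intervals do not hold the differences between cultures, whose size is unknown.

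Genes were placed in clusters by the 50 kb bin of their leftmost coordinate in the RefSeq annotation of GRCh38, the assembly of hg38, since the table used has no strand. Of 19126 protein-coding genes on the autosomes, 15931 (83.3%) lay in a clustered bin. For 17 gene lists, the share in each cluster was compared with that of all clustered genes by a two-sided permutation test over 10000 circular shifts of the clusters along the bins, which keeps neighbouring genes together, with Benjamini-Hochberg adjustment over 85 tests. The test describes 1 clustering of 1 library. On simulated lists of 20 genes with no preference, shifts along the bins gave p under 0.05 in 8.33% of 240 tests on scattered genes and 8.75% on blocks of neighbours, more than the nominal share. Shifts along the order of genes gave 5.0% and 1.67%. This second test was therefore added after seeing the data, and its adjusted p stands beside each call. The zinc finger genes of chromosome 19 were also compared with the clustered genes of that chromosome, likewise after seeing the data, by an exact permutation test over all 1173 shifts of its bins or 1308 of its clustered genes. In the simulation, the genome-wide shifts along bins and along the order of genes each found 60 of 60 lists with a raised share. The simulation left out the cluster named B4, so its rates do not cover calls in B4. The test within chromosome 19 was not simulated. The contact measures were tested on 3 simulated libraries, where the trans share was recovered within 9.04e-05 as a fraction and the exponent within 0.0006.

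The genes named are among the first 2 members of each list, in alphabetical order, in its most frequent and next most frequent cluster, plus genes of the DNA methylation machinery, and not every gene that this rule takes is named. The arms named are the 3 highest and 3 lowest by the change of the share at 10 Mb or more, and the pairs named are the 4 highest and 4 lowest by the change of trans contact relative to the median pair, among pairs with at least 1000 counts in each library. Lists, measures and these rules were fixed before the data were examined. Alternatives tried were balanced sums in place of raw counts and raw counts in place of balanced values, medians over the changes of chromosomes or arms, the median in place of the mean contact of pairs within and outside a list, other boundaries and ranges, leaving out chromosome X or each chromosome in turn, leaving out pairs with over 3 times the contact of the median pair, another clustering in the same deposit, the bin of the gene midpoint and 1 gene per bin. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.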

Results

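Hi-C contact maps were compared between DLD-1 cells, an established human colorectal adenocarcinoma line, before and after loss of the DNA methyltransferases DNMT1 and DNMT3B. DNMT1 copies methylation onto the new DNA strand after replication, and DNMT3B can place methylation on unmethylated DNA. In the DNMT1-AID line, DNMT1 carries an auxin-inducible degron, a tag that leads to degradation of the protein when the plant hormone auxin is added. Hi-C joins pieces of DNA that lay close together in the nucleus and counts the joined pairs by sequencing, so that each count is a contact between 2 genomic positions. The 7 libraries were DNMT1-AID cells untreated, after 4 d of auxin, after 10 d of auxin and after 4 d of auxin followed by 4 d of washout, and DNMT1-AID cells with a DNMT3B knockout, untreated, after 4 d and after 10 d of auxin.

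Each group held 1 library, so no difference between groups could be tested against the spread of replicates, and the direction over chromosomes or chromosome arms is given as a description of these libraries. In the order named, the DNMT1-AID libraries held 114710963, 222645438, 158423127 and 27345260 contacts, and the knockout libraries 101594306, 133252390 and 132768865, counting those within a chromosome from a separation of 100 kb on. At these depths the 95% exact binomial interval of the share of contacts between chromosomes in the shallowest library, that of the washout, ran from 23.130% to 23.161%, which covers counting error only. The contact sums hold no value for single genes, so neither the DNMT3B deletion nor the loss of DNMT1 could be read from them. All 7 libraries came from cells with the degron, so an effect of auxin itself cannot be told apart from loss of DNMT1. The untreated knockout library is titled as knockout, whereas its genotype label names only DNMT1-AID. It was grouped by its title. Chromosome 8 had 1.45-fold the contact coverage of the untreated DNMT1-AID library in this library and 1.46-fold in both treated knockout libraries, and no less than 0.996-fold and no more than 1-fold in the other 3 DNMT1-AID libraries.

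**Figure D1:**
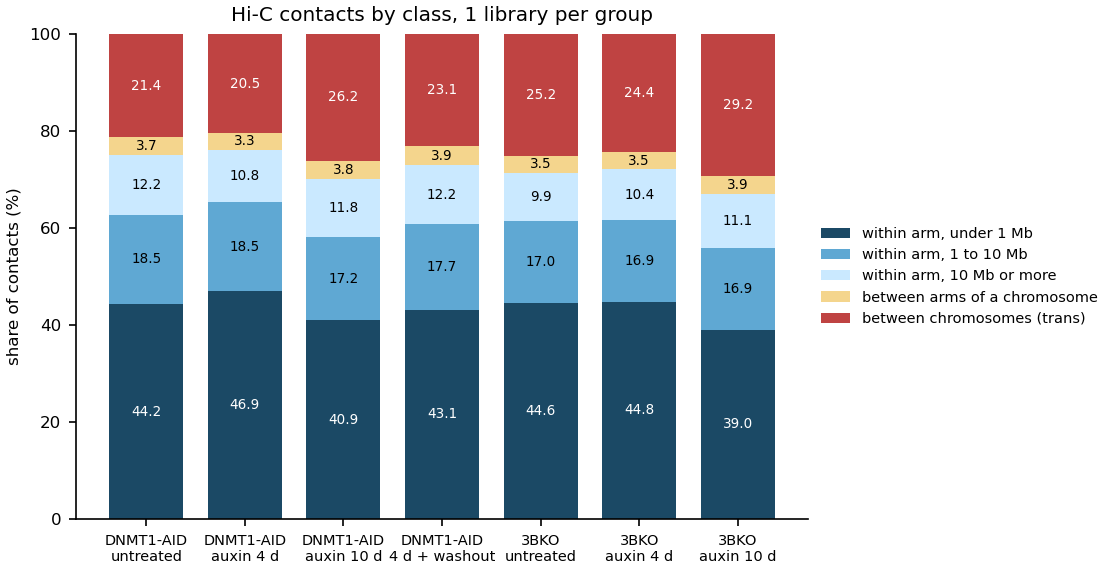
Share of all contacts (vertical axis, percent) in each of the 7 libraries (horizontal axis), split into contacts within a chromosome arm at 3 ranges of separation, between the arms of a chromosome and between chromosomes. Contacts between chromosomes made up 26.2% and 29.2% after 10 d of auxin, above the 21.4% and 25.2% of the untreated libraries of the same genotype.

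The first comparison asked how contacts differed after 4 d of DNMT1 degradation. After 4 d, DNMT1-AID cells had fewer long-range contacts and more short-range ones. Contacts at 10 Mb or more made up 14.1% of the contacts within chromosome arms, against 16.3% in untreated cells (log2 ratio -0.20), and the share was lower in all 41 arms measured. The short, gene-rich arms lay lowest: 19p had a log2 ratio of -0.59, 19q of -0.48 and 22q of -0.46, while 9p (-0.13), Xq (-0.14) and 4q (-0.15) lay highest. Contacts under 1 Mb made up 61.6% against 59.1% and were higher in 41 of 41 arms. Contact within arms was lower in each of the 10 separation bins between 10 and 100 Mb, with log2 ratios from -0.30 to -0.062.

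Contacts between chromosomes (trans contacts) made up 20.5% after 4 d and 21.4% without auxin (log2 ratio -0.058), and the share was lower on 23 of 23 chromosomes. Among the chromosome pairs, the 4 lowest all involved chromosome 22: relative to the median pair, the log2 change was -0.17 for 15 with 22, -0.17 for 21 with 22, -0.15 for 20 with 22 and -0.15 for 17 with 22. The 4 highest all involved chromosome 19, with 0.12 for 4 with 19, 0.11 for 3 with 19, 0.10 for 2 with 19 and 0.097 for 6 with 19. These pairs lay, with raw counts divided by the trans totals, between -0.082 and -0.044 and between 0.042 and 0.052. Contact among the small gene-rich chromosomes 16, 17, 19, 20 and 22, relative to other pairs, was lower by a log2 difference of -0.072, at percentile 1.19 of all 33649 sets of 5 chromosomes. Contact among the acrocentric chromosomes 13, 14, 15, 21 and 22, which carry the ribosomal DNA, was lower by -0.073, at percentile 1.09, with 10 of 10 pairs lower. For the gene-poor chromosomes 4, 5, 13, 18 and X the difference was 0.041, at percentile 93.0. With raw counts divided by the chromosomes' trans totals in place of balanced values, these 3 differences were -0.046, -0.026 and 0.014. The ratio of inter-arm to intra-arm contact at 20 to 50 Mb was 0.787 against 0.773 (log2 ratio 0.025), and this direction turned at 10 to 40 Mb, where the log2 ratio was -0.021. With each separation matched it was 0.071.

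The decay of contact with separation between 0.5 and 5 Mb was steeper after 4 d, with an exponent of -1.47 against -1.403, and it was steeper in 41 of 41 arms. The difference was -0.062, with an SD over arms of 0.018.

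The libraries after 10 d of auxin address prolonged loss of DNMT1. After 10 d, DNMT1-AID cells had more contacts between chromosomes: the trans share was 26.2% against 21.4% in untreated cells, 1.23-fold (log2 ratio 0.30), and it was higher on 23 of 23 chromosomes, with log2 ratios from 0.18 to 0.35. On the gene-dense chromosome 19 the share was 36.9% against 30%, and on the gene-poor chromosome 4 it was 21.7% against 17.2%. Against the library at 4 d the trans share was 1.28-fold, again higher on 23 of 23 chromosomes. The share at 10 Mb or more within arms was 16.9% against 16.3% (log2 ratio 0.052), higher in 33 of 41 arms. The lowest arms were 19p (-0.31), 19q (-0.098) and 21q (-0.089) and the highest were 12p (0.13), 5q (0.091) and 2p (0.090). With a boundary of 20 Mb the direction turned for 19p (0.47) and 19q (0.084). Balanced contact per bin pair within arms was higher in 3 and lower in 7 of the 10 separation bins between 10 and 100 Mb, with log2 ratios from -0.088 to 0.47. It was also lower in all 9 bins under 1 Mb (-0.13 to -0.097). A higher trans share lowers balanced contact within arms, as every bin keeps the same total.

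Trans contact after 10 d was unevenly spread over chromosome pairs. The lowest pairs relative to the median were 21 with 22 (-0.25), 17 with 22 (-0.25), 16 with 22 (-0.23) and 20 with 22 (-0.21), and the highest were 19 with X (0.17), 4 with 19 (0.14), 3 with 19 (0.13) and 6 with 19 (0.12). The lowest pairs were smaller in size with raw counts divided by the trans totals, -0.12, -0.096, -0.11 and -0.089, and the highest 0.024, 0.037, 0.043 and 0.051. Contact among the gene-rich small chromosomes was lower by a log2 difference of -0.12, at percentile 0.648 of all sets, with 10 of 10 pairs lower. Contact among the acrocentric chromosomes was lower by -0.10, at percentile 1.54, with 10 of 10 pairs lower, while that among the gene-poor chromosomes was higher by 0.085, at percentile 97.7. With raw counts divided by the trans totals the 3 values were -0.064, -0.032 and 0.0098. Over all pairs, the change was lower where untreated contact was higher, with a slope of -0.11 on log2 untreated contact. Untreated contact relative to other pairs was 1.29 (log2) in the gene-rich, 0.54 in the acrocentric and -0.74 in the gene-poor list. An effect of gene density was not separated from this general slope. The inter-arm ratio was 0.724 against 0.773 (log2 ratio -0.095, SD over chromosomes 0.13) and lower on 15 of 18 chromosomes. The decay exponent between 0.5 and 5 Mb was -1.38 against -1.403, a difference of 0.019 with an SD over arms of 0.020.

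**Figure D2:**
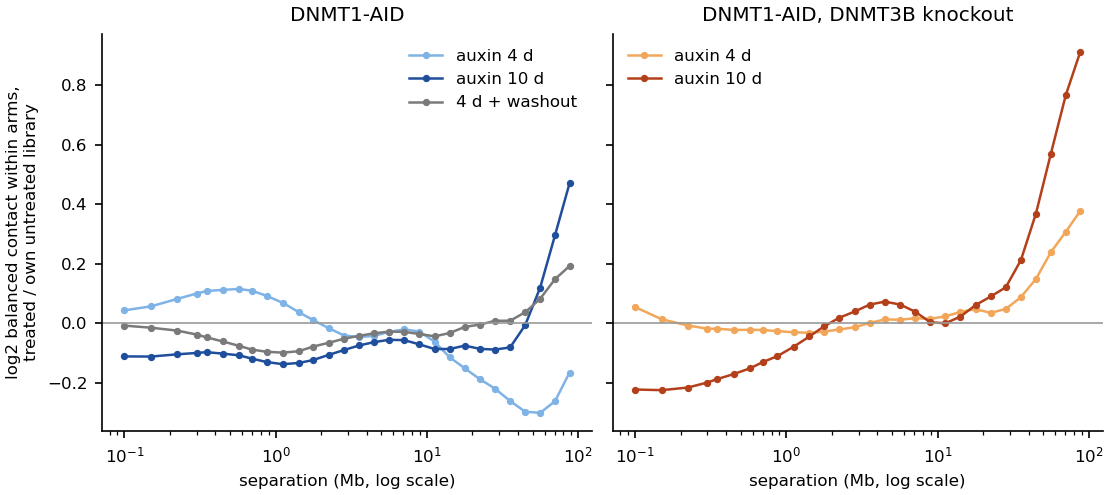
Log2 ratio of mean balanced contact within chromosome arms (vertical axis) against separation in Mb (horizontal axis, log scale), each treated library over the untreated library of its genotype, with 1 library per line. After 10 d of auxin the bin at the longest separation reached 0.47 in DNMT1-AID cells and 0.91 in knockout cells, while after 4 d DNMT1-AID cells lay at or below -0.062 from 10 Mb on.

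The washout library addresses whether contacts return once auxin is removed after 4 d. With 1 library per group, a return cannot be told apart from a 4 d library that stands apart for technical reasons. After 4 d of washout, long-range contact in DNMT1-AID cells lay near that of untreated cells. The share at 10 Mb or more was 16.7%, against 14.1% at 4 d of auxin and 16.3% in untreated cells. It was above the 4 d library in 41 of 41 arms and above the untreated library in 38 of 41 arms. The arms lowest against untreated cells were 21q (-0.050), 19p (-0.028) and 4p (-0.0020), and the highest were 12p (0.12), 6q (0.063) and 19q (0.059). The share under 1 Mb was 59.1% in both libraries, and the decay exponent was -1.38 against -1.403 in untreated cells and -1.47 at 4 d.

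The trans share after washout was 23.1%, above both the untreated library (21.4%, log2 ratio 0.12) and the library at 4 d (20.5%), on 23 of 23 chromosomes in each case. Contact among the gene-rich small chromosomes differed from untreated cells by 0.0026 on the log2 scale, at percentile 56.6, and lay above the 4 d library by 0.074, with 10 of 10 pairs higher. Among the acrocentric chromosomes the difference from untreated cells was -0.023, at percentile 2.61, and among the gene-poor chromosomes 0.0084, at percentile 74.5. Pairs relative to the median ranged from -0.076 for 13 with 22, -0.069 for 18 with 22, -0.067 for 13 with 16 and -0.054 for 9 with 22 up to 0.066 for 1 with 19, 0.061 for 4 with 19, 0.055 for 6 with 19 and 0.051 for 16 with 19, and with raw counts divided by the trans totals from -0.063 to 0.027. The inter-arm ratio was 0.788 against 0.773, a log2 ratio of 0.026, or 0.0095 with each separation matched. This library was the shallowest, with 27345260 contacts, and 5131 counts stood behind the pair of 13 and 22.

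Auxin was also given to cells without DNMT3B. After 10 d of auxin the knockout cells had more trans contacts and more long-range contacts. The trans share was 29.2% against 25.2% in untreated knockout cells, 1.16-fold (log2 ratio 0.22), and it was higher on 23 of 23 chromosomes. The share at 10 Mb or more was 16.5% against 13.8% (log2 ratio 0.26), higher in 41 of 41 arms. The highest were 7p (0.37), 3p (0.36) and 5q (0.30) and the lowest 19p (0.037), 20q (0.092) and 21q (0.10). The share under 1 Mb was 58.2% against 62.4%, lower in 41 of 41 arms, and the decay exponent was -1.41 against -1.49, higher in 41 of 41 arms (difference 0.081, SD over arms 0.026).

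After 4 d of auxin the knockout cells stood nearer to their untreated library. The trans share was 24.4% against 25.2% (log2 ratio -0.044, or -0.029 with balanced sums), lower on 22 of 23 chromosomes, and the share at 10 Mb or more was 14.5% against 13.8% (log2 ratio 0.065), higher in 32 of 41 arms. The arms at the ends were 19p (-0.23), 17q (-0.12) and 22q (-0.11), and 18p (0.16), 5p (0.14) and 4q (0.11). The share under 1 Mb was 62.1% against 62.4% (log2 ratio -0.0063, SD over arms 0.021), lower in 25 of 41 arms. The difference in the decay exponent was 0.011, with an SD over arms of 0.027, and the exponent was higher in 22 of 41 arms.

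The inter-arm ratio in the knockout was 0.778 untreated, 0.729 at 4 d and 0.670 at 10 d. At 10 d the log2 ratio was -0.22 with an SD over chromosomes of 0.16, and the ratio was lower on 17 of 18 chromosomes. At 4 d it was -0.094, with an SD of 0.080, and the ratio was lower on 16 of 18. Among chromosome pairs at 10 d, 17 with 22 (-0.19), 9 with 22 (-0.17), 9 with 17 (-0.13) and 3 with 22 (-0.12) lay lowest relative to the median, and 19 with 21 (0.18), 19 with 20 (0.15), 15 with 21 (0.14) and 13 with 21 (0.12) highest. At 4 d the ends were 11 with 22 (-0.10), 4 with 22 (-0.094), 10 with 22 (-0.093) and 14 with 22 (-0.090), and 19 with 21 (0.19), 15 with 19 (0.11), 18 with 21 (0.10) and 20 with 21 (0.094). The named pairs lay, with raw counts divided by the trans totals, between -0.090 and 0.12 at 10 d and between -0.056 and 0.12 at 4 d. Contact among the gene-poor chromosomes at 10 d was higher by 0.058, at percentile 96.8, and by 0.0075 with raw counts divided by the trans totals. For the gene-rich small chromosomes the difference at 10 d was 0.021 (percentile 74.0) and for the acrocentric chromosomes 0.0098 (percentile 61.2), with SDs over pairs of 0.096 and 0.081. At 4 d the gene-rich, gene-poor and acrocentric differences were -0.014, 0.013 and 0.021, of which the last lay at percentile 86.6. The direction for the gene-rich list at 4 d and for the acrocentric list at both times turned when the median contact of pairs replaced the mean within and outside the list (0.018, -0.053 and -0.053). The median of the changes of the 10 pairs themselves, relative to the median pair, was -0.014 for the gene-rich list at 4 d and 0.0098 and -0.0031 for the acrocentric list at 4 d and 10 d, so that only the last of these turned. With raw counts divided by the trans totals the gene-rich and gene-poor values at 4 d turned to 0.015 and -0.014.

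**Figure D3:**
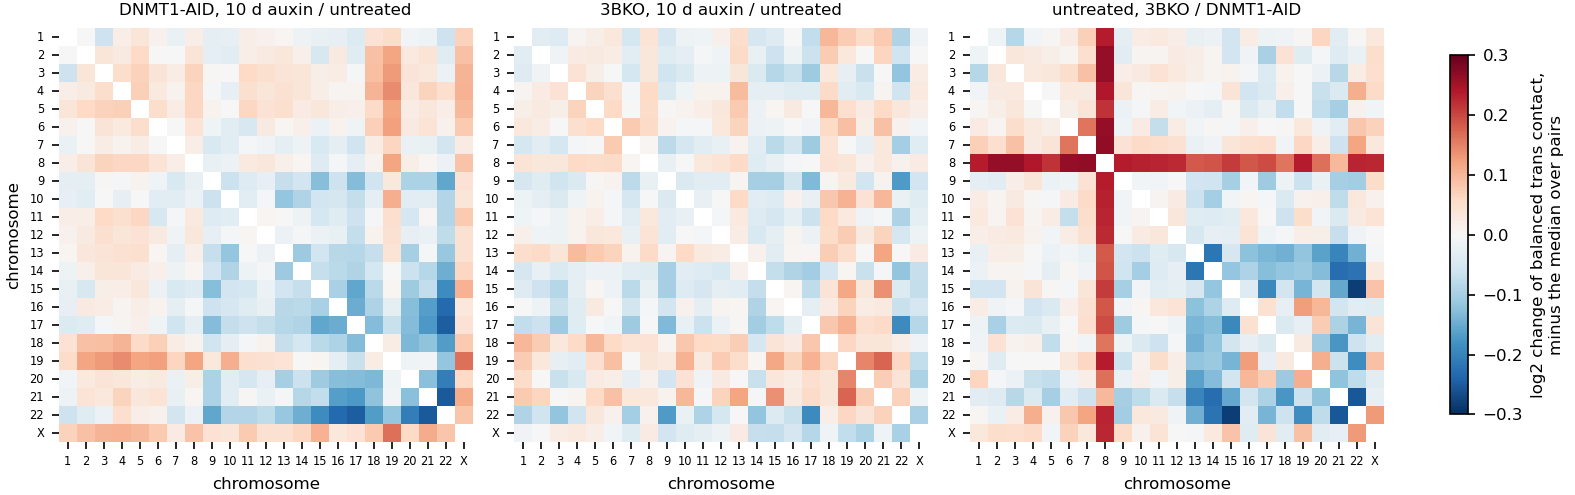
Log2 change of balanced trans contact for each pair of chromosomes (both axes), minus the median over pairs, for DNMT1-AID cells at 10 d of auxin over untreated (left), DNMT3B knockout (3BKO) cells at 10 d over untreated (centre) and untreated knockout over untreated DNMT1-AID cells (right), with red above and blue below the median pair. In the right panel the 22 pairs of chromosome 8 had a median of 0.23, and in the left panel chromosome 22 with 21 had the lowest value, -0.25.

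Without auxin, knockout cells were compared with DNMT1-AID cells, which still have DNMT3B. The knockout cells also differed in chromosome 8, with 1.45-fold coverage. With 1 library per group, loss of DNMT3B cannot be told apart from other differences between these cells. Untreated knockout cells had more trans contacts and fewer long-range contacts than untreated DNMT1-AID cells. The trans share was 25.2% against 21.4%, 1.18-fold (log2 ratio 0.24), and was higher on 23 of 23 chromosomes. The share at 10 Mb or more was 13.8% against 16.3% (log2 ratio -0.24) and was lower in 41 of 41 arms, with the lowest ratios on 5p (-0.55), 16p (-0.49) and 10p (-0.47) and the highest on 15q (-0.082), 9q (-0.12) and 5q (-0.13). The value for 15q turned to 0.049 with a boundary of 20 Mb. The share under 1 Mb was 62.4% against 59.1%, higher in 41 of 41 arms, and the decay exponent was -1.49 against -1.403, lower in 40 of 41 arms. With separations of 5 to 50 Mb the difference in exponent was -0.015 in place of -0.086.

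Contact among the acrocentric chromosomes was lower in untreated knockout cells by a log2 difference of -0.20, the lowest of all 33649 sets of 5 chromosomes, with 10 of 10 pairs lower, and by -0.094 with raw counts divided by the trans totals. The lowest pairs were 15 with 22 (-0.28), 21 with 22 (-0.25), 14 with 21 (-0.23) and 14 with 22 (-0.22), which had -0.21, -0.12, -0.088 and -0.13 with raw counts divided by the trans totals. At 4 d the acrocentric difference between the genotypes was -0.11 (percentile 0.0357) and at 10 d -0.088 (percentile 2.23). The highest pairs all held chromosome 8: 7 with 8 (0.27), 2 with 8 (0.26), 3 with 8 (0.26) and 6 with 8 (0.26). Chromosome 8 also had 1.45-fold the coverage. With raw counts divided by the trans totals these pairs lay between 0.010 and 0.052. That division largely takes out a change shared by all pairs of a chromosome. The gene-rich list differed by -0.0095 (percentile 41.3), a direction that turned under other settings, to 0.033 with raw counts divided by the trans totals, and the gene-poor list by -0.020 (percentile 32.7). The inter-arm ratios were 0.778 and 0.773, with a log2 ratio of 0.0087 and an SD over chromosomes of 0.13, or 0.0015 with each separation matched.

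With auxin, the trans share stayed above that of DNMT1-AID cells, by log2 ratios of 0.25 at 4 d and 0.16 at 10 d, on 23 of 23 chromosomes at each time. The share at 10 Mb or more was closer between the genotypes, with log2 ratios of 0.031 at 4 d, higher in 22 of 41 arms, and -0.029 at 10 d, higher in 12 of 41 arms. At 10 d, contact among the gene-rich small chromosomes was higher in the knockout by 0.13, at percentile 99.7, with 19 with 20 at 0.27, or 0.23 with raw counts divided by the trans totals. Taken as 3 pairs of libraries matched by time, a choice made after seeing the data, the knockout had a mean log2 ratio of 0.21 (SD 0.051) for the trans share, -0.078 (SD 0.14) for the share at 10 Mb or more and -0.071 (SD 0.069) for the inter-arm ratio. An exact two-sided permutation test of signs over 3 pairs cannot go below p = 0.25, the value of the trans share.

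**Figure D4:**
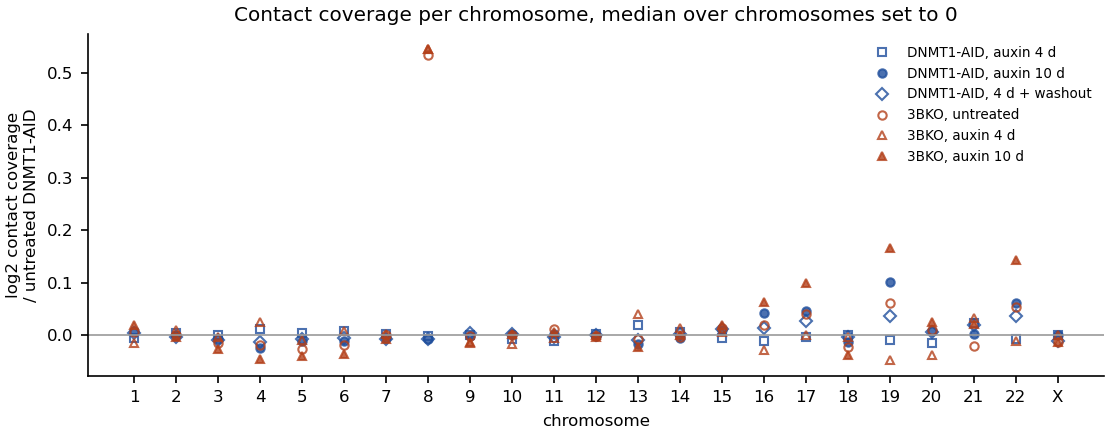
Log2 contact coverage of each chromosome (horizontal axis) relative to the untreated DNMT1-AID library (vertical axis), with the median over chromosomes of each library set to 0 and 1 point per library. Chromosome 8 lay between 0.53 and 0.54 in the 3 knockout libraries (3BKO), and between -0.0064 and -0.0016 in the treated DNMT1-AID libraries.

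The title of the series names cooperation of DNMT1 and DNMT3B, which the change with auxin in knockout cells minus that in DNMT1-AID cells addresses. At 4 d the share at 10 Mb or more went opposite ways, higher in the knockout (0.065) and lower in DNMT1-AID cells (-0.20), a difference of 0.27 on the log2 scale. At 10 d it was higher in both, with 0.26 in the knockout and 0.052 in DNMT1-AID cells, a difference of 0.21. The trans share differed less between the genotypes: the difference was 0.014 at 4 d (0.023 with balanced sums) and -0.080 at 10 d, the knockout having the smaller increase at 10 d. The difference for the inter-arm ratio was -0.12 at both times, and -0.19 and -0.16 with each separation matched, and for the gene-rich small chromosomes it was 0.058 at 4 d and 0.14 at 10 d. With 1 library per group none of these differences could be tested.

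The nuclear surroundings of single genes could be described for the untreated DNMT1-AID library, for which the authors deposited clusters of 50 kb bins by interaction profile. The clusters carry the names A1, A2, V+VI, B2/B3 and B4, of which A usually denotes active and B inactive chromatin. Of 57509 bins, 46042 (80.1%) had a cluster, none of them on chromosome 13, and chromosome 1 was covered from 41.75 Mb on. B2/B3 took 36.8% of clustered bins, V+VI 29.2%, A2 26.3%, A1 7.08% and B4 0.612%. Protein-coding genes stood at 25.6 per Mb in A1, 9.77 in A2, 6.15 in V+VI, 1.72 in B2/B3 and 18.3 in B4. Chromosome 22 had the highest share of A1 (44.3%) and chromosome 4 of B2/B3 (49.8%), while chromosome 18 had no A1 bin. Of the B4 bins, 54.6% lay on chromosome 19. The longest stretches (hg38) were 4650 kb of A1 on chromosome 19 from 2250001 to 6900000, 6400 kb of A2 on chromosome 10 from 87500001 to 93900000, 2900 kb of V+VI on chromosome 3 from 187650001 to 190550000, 5450 kb of B2/B3 on chromosome 5 from 22200001 to 27650000 and 900 kb of B4 on chromosome 19 from 56350001 to 57250000. For another clustering with 5 codes in the same deposit, each code was given the name that most of its bins had here. Named in this way, 2 codes became B2/B3 and 88.1% of bins had the same name, an agreement that the naming itself raises. No code had B4 as its most frequent name, which at 0.612% of bins does not show that B4 is absent there.

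Gene lists differed in the cluster they occupied. Of the olfactory receptor genes with a cluster, 173 of 251 (68.9%) lay in B2/B3, against 9.13% of all clustered genes (permutation adjusted p = 0.00425 from 10000 circular shifts of the clusters along the bins, and permutation adjusted p = 0.00425 with shifts along the order of genes, permutation tests with Benjamini-Hochberg adjustment over 85 tests). They include OR10A7 (chromosome 12, 55221025 to 55221975) and OR10AG1 (chromosome 11, 55965755 to 55969945). Of the neuronal genes, 13 of 18 lay in B2/B3, with permutation adjusted p = 0.0085 by shifts along bins and 0.00425 along genes. Among them were the cell adhesion genes CADM2 (chromosome 3, 84958989 to 86074429) and CDH10 (chromosome 5, 24487100 to 24644978). Each was placed by the bin of its leftmost coordinate, which does not cover the whole gene. The comparison with all genes was not matched for gene length. Zinc finger genes of chromosome 19, a family of DNA-binding proteins, were in B4 for 115 of 224 members, against 1.62% of all genes (permutation adjusted p = 0.0085 and 0.00567), including ZNF112 (44326553 to 44367217) and ZNF135 (58059239 to 58069755), while ZNF101 (19668153 to 19683506) and ZNF121 (9560329 to 9584504) were in V+VI. This baseline mixes the family with its chromosome, where B4 took 15.4% of clustered bins. In a comparison chosen after seeing the data, 34 of the 1084 other clustered genes of chromosome 19 (3.14%) were in B4. The test set the family against all clustered genes of that chromosome, the family included, of which 11.4% were in B4. It gave exact permutation adjusted p = 0.00426 over all shifts along the bins of that chromosome and 0.00765 along its genes, adjusted over 5 clusters. Before adjustment, the p along bins was the smallest that 1173 shifts allow. Genes of ribosomal proteins, which every cell expresses, were in A1 for 30 of 64 members, against 26.2% of all genes (permutation adjusted p = 0.00425 and 0.0068), including RPL10A (chromosome 6, 35468401 to 35470780) and RPL12 (chromosome 9, 127447674 to 127451406).

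Clustered protocadherins, neighbouring cell adhesion genes on chromosome 5, were in B4 for 41 of 53 members, including PCDHA1 and PCDHA10, while PCDHA3 and PCDHA4 were in B2/B3. This passed with shifts along bins (permutation adjusted p = 0.0467) and along genes (permutation adjusted p = 0.0068) and missed with the bin of the gene midpoint (permutation adjusted p = 0.0572) or with 1 gene per bin (permutation adjusted p = 0.051). A further 5 calls from the shifts along bins were lost with shifts along genes. These were housekeeping genes in A1, with 8 of 14 members including ACTB and GAPDH (permutation adjusted p = 0.017 along bins and 0.114 along genes), imprinted genes in B4 with 3 of 15 (0.0401 and 0.106), neuronal genes with 0 of 18 in A1 (0.0401 and 0.107) and 1 of 18 in A2 (0.0467 and 0.0672), and olfactory receptors with 7 of 251 in A1 (0.0467 and 0.114). With shifts along genes 5 other calls were gained: olfactory receptors in A2 (26 of 251, permutation adjusted p = 0.0142), chromosome 19 zinc finger genes in A2 (22 of 224, 0.0158), keratin-associated proteins in B2/B3 (33 of 59, 0.0202), ribosomal proteins in V+VI (7 of 64, 0.0397) and histone genes in A2 (53 of 62, 0.045).

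Other lists did not pass under shifts along bins. HOX genes, which pattern the body axis, had 30 of 35 members in A2 (permutation adjusted p = 0.155), among them HOXA10, with HOXB7 and HOXB8 in A1. Histone genes had 53 of 62 in A2 (permutation adjusted p = 0.196), including H1-1 and H1-10, and type I interferons 16 of 17 in V+VI (permutation adjusted p = 0.173), including IFNA1 and IFNA10. Defensins had 12 of 24 in V+VI (permutation adjusted p = 0.404), keratin-associated proteins 33 of 59 in B2/B3 (0.173) and cancer-testis genes 4 of 7 in V+VI (0.173), among them DAZL and MAEL. Colon epithelium genes were spread over A2 (6 of 14, including AXIN2 and CDX1), V+VI (5 of 14, including CDH17 and FABP1) and A1 (3 of 14). Of the markers of other cell types, hepatocyte genes had 6 of 14 in V+VI, including ALB and AFP, and immune genes 4 of 13 each in A1 (including CD4) and A2 (including CD3D and CD3E), with permutation adjusted p = 0.446 and, for A1, 0.86.

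Genes of the DNA methylation machinery lay mostly in A2, with 10 of 16 members (permutation adjusted p = 0.166). DNMT1 (chromosome 19, 10133346 to 10194953), DNMT3A (chromosome 2, 25227874 to 25342590) and DNMT3B (chromosome 20, 32762385 to 32809356), the methyltransferases, were in A2, as were TET1 (chromosome 10) and TET3 (chromosome 2), which oxidise methylated cytosine, CDCA7, MBD1, MBD4, UHRF2 and ZBTB24. UHRF1 (chromosome 19, 4903080 to 4962154), which recruits DNMT1 to replicating DNA, and MBD3 (chromosome 19) were in A1. HELLS, MBD2, TDG and TET2 were in V+VI. DNMT3L had no cluster.

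**Figure D5:**
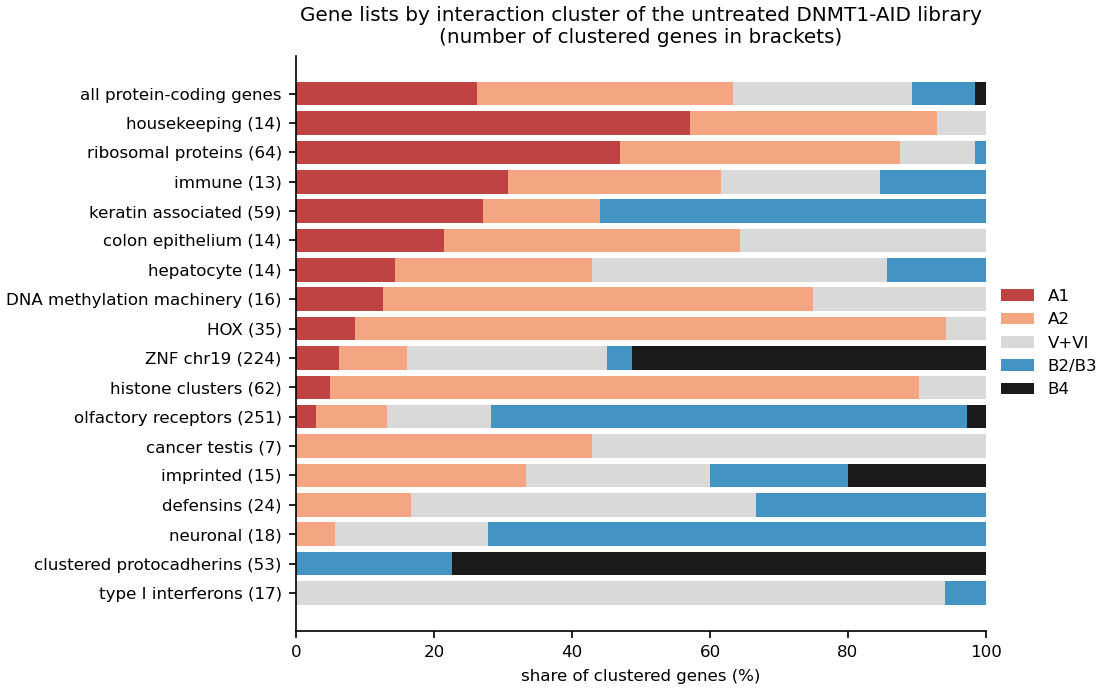
Share of the clustered genes of each list (horizontal axis, percent) in each interaction cluster of the untreated DNMT1-AID library, with all protein-coding genes as the top bar and the number of clustered genes in brackets. B2/B3 holds 68.9% of olfactory receptor genes and 9.13% of all genes, and B4 holds 51.3% of chromosome 19 zinc finger genes, 3.14% of the other genes of that chromosome and 1.62% of all genes.

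In DNMT1-AID cells at 10 d the log2 change of the trans share of a chromosome went with its cluster composition. The log2 change of the trans share was smaller on chromosomes with more A2 (Spearman -0.75, Pearson -0.77, 21 chromosomes) and more A1 (Spearman -0.71, Pearson -0.66), and larger on those with more V+VI (0.67 and 0.71) or B2/B3 (0.67 and 0.70). Chromosome length gave 0.65 and 0.63, so composition and length were not separated. The untreated trans share, which is the base of the log2 change, was not separated from composition either. With most A1, chromosomes 22, 19 and 17 went from 36.3%, 30% and 32.5% untreated to 41.2%, 36.9% and 37.7%. With least A1, chromosomes 18, 8 and 5 went from 23.4%, 19.7% and 18.6% to 28.8%, 24.5% and 23.7%. In percentage points the rise on chromosome 19 was larger than on 18, 8 and 5, and the rises on 22 and 17 lay within their range. On these chromosomes the smaller change with more A1 was thus seen in the log2 change only. Relations of composition to the change in percentage points over all chromosomes were not tested. Without the 2 chromosomes farthest from the median the Spearman values were -0.67 for A2, -0.75 for A1, 0.73 for V+VI and 0.69 for B2/B3. At 4 d A2 gave -0.73, while A1 gave -0.34 and V+VI 0.28, each with a jackknife standard error of 0.28. After washout A2 gave -0.69, or -0.36 with balanced sums, A1 -0.25 (standard error 0.27) and V+VI 0.35 (0.28). In the knockout at 4 d the signs were the opposite, with 0.11 for A2, 0.29 for A1, -0.23 for V+VI and -0.26 for B2/B3, and all of them turned with balanced sums (-0.27, -0.20, 0.11 and 0.31). In the knockout at 10 d, B2/B3 gave 0.67, A1 -0.53 (0.46 and -0.32 with balanced sums) and chromosome length 0.15, and for untreated knockout against untreated DNMT1-AID cells V+VI gave 0.82 and length 0.74. Chromosomes within a pair of libraries are not independent replicates, so no p-value is given for these 66 relations.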

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

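The tests of explanations in this part were chosen after the result they bear on had been seen, although leaving out each chromosome in turn, which includes the value without chromosome 8, had been planned. Differences between the genotypes stand out here because the change with auxin had opposite signs in the 2 genotypes, and with 1 library per group none of them was tested.

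At 4 d of auxin, 5 measures had changes of opposite sign in knockout and DNMT1-AID cells: the difference, knockout minus DNMT1-AID, was 0.27 (log2) for the share at 10 Mb or more, -0.066 for the share under 1 Mb, -0.12 for the inter-arm ratio, 0.073 for the decay exponent and 0.094 for contact among the acrocentric chromosomes. In the knockout the share under 1 Mb (-0.0063, SD over arms 0.021, lower in 25 of 41 arms) and the decay exponent (0.011, SD 0.027, higher in 22 of 41) went both ways over arms, so that for these the opposite sign rests on a small pooled value. For the acrocentric list the opposite directions depended on how pairs were summarised: with the median in place of the mean contact of pairs they were lost, with -0.053 in the knockout and a difference of 0.0071, while the medians of the pair changes kept them, with 0.0098 and -0.058. They were also lost for the inter-arm ratio at 10 to 40 Mb, where DNMT1-AID cells had -0.021 and the knockout -0.10.

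For the opposite changes of the share at 10 Mb or more at 4 d, the difference without chromosome 8 was 0.26. The contacts of chromosome 8 itself are thus not the main source. In DNMT1-AID cells the share was lower in 41 of 41 arms, so leaving out a single chromosome could hardly remove the difference. Effects of an extra copy of chromosome 8 on other chromosomes stay open. A change of random ligation that sets the trans share is argued against as the whole cause. Uniform contact that gives the trans share at 4 d predicted a change of -0.0026 in DNMT1-AID cells, where -0.20 was observed. In the knockout it predicted -0.0032, where 0.065 was observed. A library that stands apart for technical reasons also stays open, since each library exists once. The untreated libraries alone differed by -0.24. The knockout library at 4 d had the highest share of contacts with the mitochondrial genome (0.0948%, against 0.0288% to 0.0533% in the other 6). The DNMT1-AID library at 4 d was the deepest (222645438 contacts) and had the lowest mitochondrial share. Contacts at 10 Mb or more made up 14.1% in that library, against 16.3% untreated, 16.9% at 10 d and 16.7% after washout. Also open is an effect of the DNMT3B genotype, which the design names and which was not tested against replicates.

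At 10 d of auxin, contact among the gene-rich small chromosomes had opposite signs, with a difference of 0.14 between the genotypes, as had contact among the acrocentric chromosomes, with a difference of 0.11. The knockout values were 0.021 with an SD over pairs of 0.096 and 0.0098 with an SD of 0.081, and the acrocentric value turned to -0.053, the sign of DNMT1-AID cells, with the median in place of the mean contact of pairs, and to -0.0031 as the median of the pair changes.

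The higher trans share after 10 d of auxin was seen in both genotypes. More random ligation as the whole cause is argued against by the chromosome pairs, because uniform contact lifts weak pairs more than strong ones: the predicted slope of the log2 pair change on log2 untreated contact was -0.20 in DNMT1-AID cells and -0.16 in the knockout, and the observed slopes lay above it by 0.084 (jackknife standard error over chromosomes 0.032) and 0.16 (0.036). Uniform contact as the only change is also argued against by the inter-arm ratio, which it would have moved up to 0.776 and 0.781 and which was 0.724 and 0.670, with log2 ratios of observed over predicted of -0.10 and -0.22 and standard errors of 0.029 in each. In the knockout, depth, taken as the number of contacts counted, is argued against by the libraries at 10 d and 4 d. They differed in depth by 0.363% and in trans share by a log2 ratio of 0.26. The DNMT1-AID libraries held no pair of near equal depth, so this comparison does not cover them. Random ligation as a part of the rise stays open. Contact at 50 to 100 Mb (predicted change -0.020 in the knockout) does not decide on it, since that range was picked for its higher contact. A culture or library batch of the 10 d libraries stays open too. With 1 library per group it cannot be told apart from the time in auxin. An effect of prolonged DNMT1 loss is untested. An effect of auxin itself cannot be told apart from it, since no cells without the degron were given auxin.

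Higher balanced trans contact of chromosome 8 in the knockout libraries is a pattern for which an extra copy carried through matrix balancing is a candidate explanation. Balancing a chromosome with the measured 1.45-fold coverage predicted a log2 excess of its pairs of 0.23 in untreated cells, where 0.23 was observed (SD over 22 pairs 0.041), and 0.24 and 0.23 at 4 d and 10 d, where 0.21 and 0.24 were observed. For the untreated knockout library, a source in cells without this gain is argued against by its chromosome 8 coverage. That was a log2 value of 0.53, near the 0.54 of both treated knockout libraries and above the highest other chromosome at 0.062. Coverage does not show the DNMT3B deletion, so a source in cells with the gain but without the deletion stays open. Whether the gain came with the knockout clone or later is not addressed by these data, and no biological explanation was tested.

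Contacts with the mitochondrial genome, which no comparison above used, lay above the untreated library of the same genotype in 2 libraries: 0.0504% of contacts after washout against 0.0377%, and 0.0948% in the knockout at 4 d against 0.0533%. In DNMT1-AID cells at 4 d they lay below it, at 0.0288%, and at 10 d they were 0.0368% in DNMT1-AID cells and 0.0532% in the knockout. The tables hold no contacts of the mitochondrial genome with itself, so the amount of mitochondrial DNA is not known and these values do not decide on random ligation.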

How the results depend on the processing

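The settings without chromosome 8, with chromosomes Y and M, with each separation matched in the inter-arm ratio and with shifts along the order of genes were chosen after seeing the data. The mean over 3 matched times and the comparison within chromosome 19 were chosen after seeing the data too. No pairing by replicate exists with 1 library per group, so the knockout and DNMT1-AID libraries were paired by time. The other alternatives were fixed before the data were examined. Planned and added alternatives together, 226 of 411 alternative values lay within the spread of the value reported, 163 lay outside it and 22 changed direction. That spread was the counting interval for the shares, which is narrow at this depth, the SD over chromosomes, arms or pairs for the other contact measures, and the jackknife standard error for correlations. Of 179 alternative values for the shares, 177 kept the direction, as did the 48 values with raw counts for the chromosome pairs named in the first 6 comparisons listed below. Among the pairs at the ends of the other 5 comparisons, 5 with X in DNMT1-AID cells at 10 d against 4 d went from 0.082 to -0.0045 with raw counts. Dividing raw counts by the trans totals of both chromosomes largely takes out a change that all pairs of a chromosome share. Smaller values in that setting can follow in part from this division. Except for this division and where a change of boundary or range sets the value by its construction, the cause was not tested. The clusters do not cover chromosome X, so leaving it out was not run for them, and B4 has no value in the clustering with 5 codes.

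Values below are log2 ratios in the order DNMT1-AID at 4 d, at 10 d and after washout, knockout at 4 d and 10 d, untreated knockout over untreated DNMT1-AID, and the difference between the genotypes at 4 d and 10 d. The trans share gave -0.052, 0.29, 0.11, -0.029, 0.21, 0.23, 0.023 and -0.081 with balanced sums. Without chromosome X it gave -0.059, 0.30, 0.12, -0.044, 0.22, 0.24, 0.015 and -0.077, and as a median over chromosomes -0.055, 0.30, 0.11, -0.039, 0.21, 0.24, 0.016 and -0.086. With chromosomes Y and M the values were -0.058, 0.30, 0.12, -0.042, 0.22, 0.24, 0.017 and -0.080, and without chromosome 8 -0.060, 0.30, 0.12, -0.045, 0.22, 0.22, 0.016 and -0.081. Leaving out each chromosome in turn gave -0.061 to -0.056, 0.29 to 0.30, 0.11 to 0.12, -0.048 to -0.043, 0.21 to 0.22, 0.22 to 0.24, 0.011 to 0.016 and -0.084 to -0.075.

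In the same order, the share at 10 Mb or more gave -0.20, 0.045, 0.039, 0.068, 0.26, -0.26, 0.27 and 0.22 with balanced sums and -0.20, 0.054, 0.037, 0.065, 0.26, -0.23, 0.27 and 0.20 without chromosome X. As a median over arms it gave -0.22, 0.040, 0.032, 0.054, 0.24, -0.28, 0.27 and 0.20. A boundary of 5 Mb gave -0.16, 0.048, 0.027, 0.045, 0.22, -0.22, 0.20 and 0.17, and a boundary of 20 Mb gave -0.26, 0.083, 0.063, 0.099, 0.37, -0.19, 0.36 and 0.28. Without chromosome 8 the values were -0.20, 0.054, 0.037, 0.061, 0.26, -0.23, 0.26 and 0.21. Leaving out each chromosome in turn gave -0.21 to -0.20, 0.047 to 0.054, 0.036 to 0.038, 0.059 to 0.069, 0.25 to 0.26, -0.24 to -0.23, 0.26 to 0.27 and 0.20 to 0.21.

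The share under 1 Mb gave 0.061, -0.013, -0.0015, -0.0079, -0.10, 0.086, -0.069 and -0.091 with balanced sums and 0.056, -0.018, -0.0072, -0.0098, -0.082, 0.075, -0.066 and -0.064 with a boundary of 2 Mb, so that the washout value, 0.0010 in the main setting, changed direction in both. The median over arms gave 0.060, -0.012, 0.0028, -0.0028, -0.086, 0.082, -0.063 and -0.073. Without chromosome X the values were 0.060, -0.014, 0.0011, -0.0055, -0.099, 0.078, -0.066 and -0.086, and without chromosome 8 0.060, -0.014, 0.00098, -0.0052, -0.10, 0.079, -0.066 and -0.087. Leaving out each chromosome in turn gave 0.059 to 0.061, -0.015 to -0.012, 0.00063 to 0.0015, -0.0073 to -0.0044, -0.10 to -0.098, 0.077 to 0.082, -0.067 to -0.065 and -0.088 to -0.086.

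Single arms changed direction as follows. In DNMT1-AID cells at 10 d, 19p and 19q had 0.47 and 0.084 with a boundary of 20 Mb. After washout 19p and 19q had 0.0088 and -0.022 with a boundary of 5 Mb, and 4p had 0.00065 with balanced sums and 0.0066 with a boundary of 20 Mb. In untreated knockout over DNMT1-AID cells 15q had 0.049 with a boundary of 20 Mb.

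The inter-arm ratio at 4 d in DNMT1-AID cells changed direction at 10 to 40 Mb (-0.021), and matching each separation kept all 8 directions, with 0.071, -0.10, 0.0095, -0.12, -0.26, 0.0015, -0.19 and -0.16 in the order above. Over 5 to 50 Mb the decay exponent differed by -0.10 at 4 d in DNMT1-AID cells, by -0.015 between the untreated genotypes and by 0.14 between the auxin effects at 4 d. With raw counts divided by the trans totals, the gene-rich list gave -0.00041 after washout, 0.015 in the knockout at 4 d and 0.033 between the untreated genotypes, each with its direction changed. The last pair of comparisons also changed direction with the median in place of the mean contact of pairs (0.018 and 0.022), and the untreated genotypes did so without pairs of over 3 times the median contact (0.063) and without chromosome 8 (0.011). The gene-poor list with raw counts gave 0.014 and 0.0098 in DNMT1-AID cells at 4 d and 10 d and 0.0075 in the knockout at 10 d, and changed direction in the knockout at 4 d (-0.014). Its difference between the genotypes at 10 d changed direction with this median (0.037). The acrocentric list with raw counts gave -0.032 in DNMT1-AID cells at 10 d and -0.094 between the untreated genotypes. With this median it changed direction in the knockout at 4 d (-0.053) and at 10 d (-0.053), and the difference between the genotypes at 4 d was 0.0071.

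Paired by time, the mean log2 ratio of knockout over DNMT1-AID cells was 0.21 for the trans share, -0.078 for the share at 10 Mb or more and 0.029 for the share under 1 Mb, and the difference in the decay exponent was -0.041. The direction of the untreated libraries was changed for the inter-arm ratio (-0.071) and the gene-rich list (0.056), and kept for the gene-poor (-0.038) and acrocentric (-0.13) lists. The exact two-sided permutation p over 3 pairs was 0.25, its smallest possible value, for the trans share, the decay exponent and the gene-poor and acrocentric lists, 0.5 for the share under 1 Mb, the inter-arm ratio and the gene-rich list, and 0.75 for the share at 10 Mb or more.

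With each code named after most of its bins, the clustering with 5 codes gave 8.43% of bins to A1, 22.5% to A2, 31.2% to V+VI and 37.9% to B2/B3. With balanced sums, the Spearman correlation of the trans change with cluster composition in DNMT1-AID cells at 10 d was -0.54 for A1 and 0.50 for V+VI, and after washout it was -0.36 for A2 and 0.068 for V+VI. In the knockout at 10 d it was -0.32 for A1, 0.20 for V+VI and 0.46 for B2/B3. At 4 d in the knockout the direction changed for A1 (-0.20), A2 (-0.27), V+VI (0.11) and B2/B3 (0.31). For B4 in the knockout at 10 d it changed with balanced sums (0.15) and without the 2 chromosomes farthest from the median (0.064). Of the 10 gene list calls, 8 were shared with the bin of the gene midpoint, 7 with 1 gene per bin and 5 with shifts along the order of genes. Against the genes of their own chromosome, the chromosome 19 zinc finger genes kept their higher share in B4, by 39.9 in place of 49.7 percentage points (exact permutation adjusted p = 0.00426 along bins and 0.00765 along genes), while their difference in B2/B3 changed direction, from -5.56 to 2.81 points (exact permutation adjusted p = 0.604 and 0.00765). Their differences in A1 (-46.0 points), A2 (-15.0) and V+VI (18.2), which did not pass under shifts along all bins, passed within the chromosome with exact permutation adjusted p from 0.00639 to 0.0306. The V+VI difference against all genes, 3.06 points, changed direction with 1 gene per bin (-1.39).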

Other observations

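The separation range of 50 to 100 Mb was chosen after seeing the decay curves, and the correlation of pair changes between the genotypes had its test written down before its value was seen.

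Within arms, balanced contact at 50 to 100 Mb was higher after 10 d of auxin, more so without DNMT3B. Of the 10 bins between 10 and 100 Mb, 3 were higher and 7 lower in DNMT1-AID cells, against 9 higher and 1 lower in the knockout. Since balancing gives every bin the same total, a higher trans share lowers balanced contact within arms. In DNMT1-AID cells the 9 bins under 1 Mb were all lower too, from -0.13 to -0.097. As a share of raw intra-arm contacts, contact at 10 Mb or more was higher there in 33 of 41 arms. On the 20 arms long enough to measure, balanced contact at 50 to 100 Mb in the knockout at 10 d was 1.60-fold that of untreated knockout cells (log2 ratio 0.68, jackknife standard error over arms 0.025), higher on 20 of 20 arms, from 0.38 on Xq to 0.95 on 3p. In DNMT1-AID cells at 10 d it was 1.16-fold (log2 ratio 0.21, standard error 0.026), higher on 18 of 20 arms, with Xq lowest (-0.18) and 3p again highest (0.36). At 4 d the genotypes lay on opposite sides, with 0.28 in the knockout (20 of 20 arms higher) and -0.27 in DNMT1-AID cells (0 of 20 higher), and after washout the value was 0.11 (20 of 20 higher). Untreated knockout cells differed from untreated DNMT1-AID cells by -0.033 with a standard error of 0.030 and 9 of 20 arms higher, a direction that turned to 0.060 as a share of raw intra-arm contacts. As shares of raw intra-arm contacts the 10 d values were 0.77 and 0.33. Contact between arms in the same range was higher at 10 d by 0.32 in the knockout and 0.13 in DNMT1-AID cells.

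Contact coverage of the small gene-rich chromosomes 16, 17, 19 and 22 was higher at 10 d in both genotypes relative to the untreated DNMT1-AID library. Chromosome 19 had a log2 coverage of 0.17 in the knockout and 0.10 in DNMT1-AID cells, chromosome 22 of 0.14 and 0.061, and chromosome 17 of 0.099 and 0.047, while the gene-poor chromosome 4 had -0.045 and -0.023. Chromosome 16 had 0.063 in the knockout and 0.043 in DNMT1-AID cells. Chromosome 20 had only 0.026 and 0.0076, the latter near the 0.0077 of chromosome 1. Untreated knockout cells already had 0.062 on chromosome 19, 0.055 on 22 and 0.042 on 17, and the knockout at 4 d had -0.047 on 19. The knockout values at 10 d thus hold a difference from DNMT1-AID cells that was present without auxin. After washout the values were 0.037 on 19, 0.036 on 22 and 0.028 on 17. Coverage counts each contact at both ends, trans contacts included, so it was not separated from the change of the trans share.

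In the untreated libraries 3 chromosome pairs had over 3 times the contact of the median pair, all with chromosome 22: 19 with 22 (3.67-fold in DNMT1-AID and 3.18-fold in knockout cells), 17 with 22 (3.42-fold and 3.06-fold) and 20 with 22 (3.29-fold and 3.07-fold).

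A hypothesis that the pair changes at 10 d may be shared by both genotypes was left undecided. Over all pairs of chromosomes the changes correlated with Pearson 0.22 and Spearman 0.24, and a permutation of chromosome labels gave a one-sided p of 0.0744, which misses the threshold set beforehand. After regressing each on the contact level of the untreated library, Pearson was 0.38 and Spearman 0.35 with a permutation p of 0.003, and without chromosome 22 it was 0.36 with p of 0.0059. The regression mattered mainly in DNMT1-AID cells, where the slope on untreated contact was -0.11, against 0.0014 in the knockout, so that in DNMT1-AID cells the change was lower in pairs with more untreated contact. Pairs that share a chromosome are not independent, which the permutation takes into account, and each genotype had its own untreated library.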
